A study of Mus musculus with 6 samples.

How the data were processed

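Total RNA had been isolated with RNeasy kits and turned into biotin-labelled cRNA from 5 ug by the Affymetrix protocol, per the labels' protocols. The measurements are 1-colour arrays of 45101 probe sets in 6 mouse uterine horn samples, 3 given oil and 3 given P4 (progesterone), all Gata2 d/d. Groups and replicate numbers were taken from the sample titles.

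The deposited table of the authors holds intensity values on a linear scale, from 1.0 to 25080 with array medians from 113.2 to 120.0. The distributions match closely, from which scaling between arrays before deposit was inferred and not tested. The method of any such scaling and of the summary of probes to probe sets is not given in the sources used here. No detection calls were used here, and a dim probe set can lie near background. A scaling that equalizes the arrays hides any change in total RNA per cell, and differences are therefore relative to the other genes of an array. The median log2 difference over all genes was -0.0013.

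Values were turned into log2(intensity + 16), where the pseudocount of 16 draws the differences of dim probe sets towards 0. A fold change here is on that scale and understates the change of dim genes. The array medians of these values lay within 0.0745 of each other, below the limit of 0.1 set beforehand, so no further scaling was applied. Of the probe sets, 34945 carried 1 gene symbol in the platform's annotation, 932 several and 9160 none, and 64 were controls. Only the first kind was used. Their gene identifiers matched the RefSeq gene table of assembly GRCm38.p6 for 34754 probe sets, and 0 symbols needed an update. No coordinates are given, because the files name no genome build. Each of the 18193 genes was represented by its probe set with the highest mean over the 6 arrays.

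P4 was compared with oil in limma 3.58.1 under R 4.3.3 (lmFit and eBayes), with no covariate and all 6 arrays. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and positive differences are higher in P4. Single genes rest on limma, since a 2-sided exact permutation test of 3 against 3 cannot go below 0.1. In all, 30 gene lists with 633 memberships were fixed, of which 592 were measured, and the other members were not analysed here. They cover P4 response, glucocorticoid-type steroid targets, the hedgehog, Wnt, and BMP and TGF-beta pathways, estrogen-responsive genes, steroid receptors and cofactors, GATA and FOG factors, decidual stroma, retinoids, and ion and water transport. Further lists hold cell cycle, immediate early, heat shock, interferon, clock and prostaglandin genes. The marker lists are for luminal and general epithelium, glands, stromal fibroblasts, smooth muscle, endothelium, macrophages and myeloid cells, lymphocytes, granulocytes and mast cells, mesothelium, adipocytes, skeletal muscle, oviduct and ovary, and red blood cells. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. A list's p under another setting or with an array left out is from camera at the preset correlation, unless named otherwise. A gene on several lists counts in each. Where p was adjusted over a list alone, no adjustment across the lists was made.

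The lists, the tests and the alternatives were chosen before the data were examined, apart from those named otherwise. So was the rule for the genes named. It takes 24 genes of P4 and uterine biology whether called or not, of which Areg and Calca were not analysed here. It adds the genes past the threshold, or, as fewer than 5 passed, the 10 per direction with the smallest p whose groups did not overlap and whose higher mean was at or above the median gene. It also takes up to 4 members per list with the smallest p. Acod1 was named after its value was seen, to complete a count of 3 members.

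The fit and the list tests were tested on simulated data for this comparison, in 20 runs over 18193 genes with 200 of them changed. A change of 1 on the log2 scale was found for 92.8% of changed genes and a change of 2 for 99.4%, with 5.11% of the calls wrong. With 200 genes changed, the adjusted threshold is easier to pass than with the 4 genes called here. These shares therefore do not carry over to the real comparison, where Npl missed the threshold at a difference of 2.22 (adjusted p in limma = 0.0516). With no change put in, 1 run called a gene and 2 runs called a list. A list shifted by 0.4 was found in 20 of 20 runs. The simulated genes varied independently, while members of some real lists vary together, with an estimated correlation of 0.745 for endothelium. The list counts of the simulation therefore do not carry over to such lists. Alternatives were quantile normalization, centring of the arrays, removal of probe sets below the 40th percentile, the replicate number as a block, each array left out, the mean of a gene's probe sets or all probe sets, a trended robust variance, array weights, pseudocounts of 1 and 64, and other thresholds and list tests. No array duplicated another. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.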

Results

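Gene expression was measured on 6 one-colour Affymetrix mouse arrays, each carrying biotin-labelled RNA from the uterine horn of an ovariectomized female aged 8 weeks. All samples were Gata2 d/d, a genotype in which Cre recombinase made from the progesterone receptor gene removes a floxed Gata2, the gene of a zinc-finger transcription factor of the uterus. The arrays fall into 2 groups, 3 from females given oil (the vehicle) and 3 from females given P4 (progesterone), with no dose or time in the labels. Ovariectomy removes the main source of ovarian steroids, so the oil group is the background for the P4 group. The deposited values are probe-set intensities whose distributions are alike in the 6 arrays, so the authors may have scaled them between arrays. The median intensity of an array lay between 113.2 and 115.4 in 5 arrays and was 120.0 in P4 array 3. The 3'/5' signal ratios of the control transcripts Actb and Gapdh, a sign of RNA quality, were higher in every P4 array than in every oil array: 2.04 to 2.27 against 1.82 to 2.01 for Actb, and 1.69 to 1.73 against 1.49 to 1.59 for Gapdh. Across 18193 genes, the correlation between any pair of arrays lay between 0.981 and 0.995. The precision rests on 3 arrays per group. Nothing in the labels says that the samples came from separate animals, so p-values measure only the spread between these samples. In oil array 1, 34 genes stood over 1 log2 unit above every other array, and in oil array 3, 64 genes did. These counts argue against the oil arrays being technical repeats of 1 RNA. For the P4 arrays, a technical spread stays open.

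The single comparison, P4 against oil within the Gata2 d/d uterus, asks which genes differed with P4 in this genotype. Thrsp, Sec23b, Fkbp5 and Fxyd4 rose with P4, and no gene fell. Thrsp, a nuclear regulator of lipid-making enzymes, went from an intensity of 660 ± 38 in oil to 1797 ± 144 in P4 (SD, n = 3), a 2.68-fold difference on log2(intensity + 16). Sec23b, a coat protein of vesicles leaving the endoplasmic reticulum, went from 1495 ± 51 to 3543 ± 218 (SD, n = 3), 2.35-fold. Fkbp5, a chaperone of steroid receptors, went from 252 ± 45 to 658 ± 57 (SD, n = 3), 2.53-fold, and Fxyd4, a regulator of the sodium pump, showed the widest difference of these genes, 4.03-fold, from 651 ± 200 to 2600 ± 269 (SD, n = 3). In each of the 4 genes all 3 P4 arrays lay above all 3 oil arrays.

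The log2 differences were 1.42 ± 0.088 for Thrsp and 1.24 ± 0.078 for Sec23b (SE), both with an adjusted p of 0.00284 in limma. They were 1.34 ± 0.13 for Fkbp5 (adjusted p = 0.0387) and 2.01 ± 0.20 for Fxyd4 (adjusted p = 0.0442). At an unadjusted p under 0.05, limma gave 1317 genes, 711 higher and 606 lower in P4, where chance would give 910. The grouping of oil arrays 1 and 2 with P4 array 3 against the other arrays, which is not the design, gave 2110 such genes. The groups did not overlap for 2397 genes, 13.2% of those tested, against the 10% that chance gives for 3 against 3. The other probe sets of a gene did not always move with the one used. A second Thrsp probe set differed by 1.27 and the dimmest by -0.04, while the dimmer probe sets of Fkbp5 differed by 0.30 and -0.22. Thrsp passed with any single array left out and Sec23b with any but P4 array 1 (adjusted p = 0.0509). Of the fits with an array left out, Fkbp5 passed only in that without oil array 3, and Fxyd4 only in those without oil array 1 or oil array 3. Without P4 array 1 the adjusted p was 0.217 for Fkbp5 and 0.325 for Fxyd4, and the count of genes was 1 without P4 array 1, 10 without P4 array 3 and 13, 9 of them lower in P4, without oil array 2. Fkbp5 and Fxyd4 also missed the threshold with a pseudocount of 1 (0.0724 and 0.0747), with a pseudocount of 64 (both 0.0566), with the mean of a gene's probe sets (0.369 and 0.0519) and with all probe sets tested (0.0644 and 0.0673), and Fxyd4 with a trended, robust variance (0.0517) or without dim probe sets (0.0532).

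**Figure D1:**
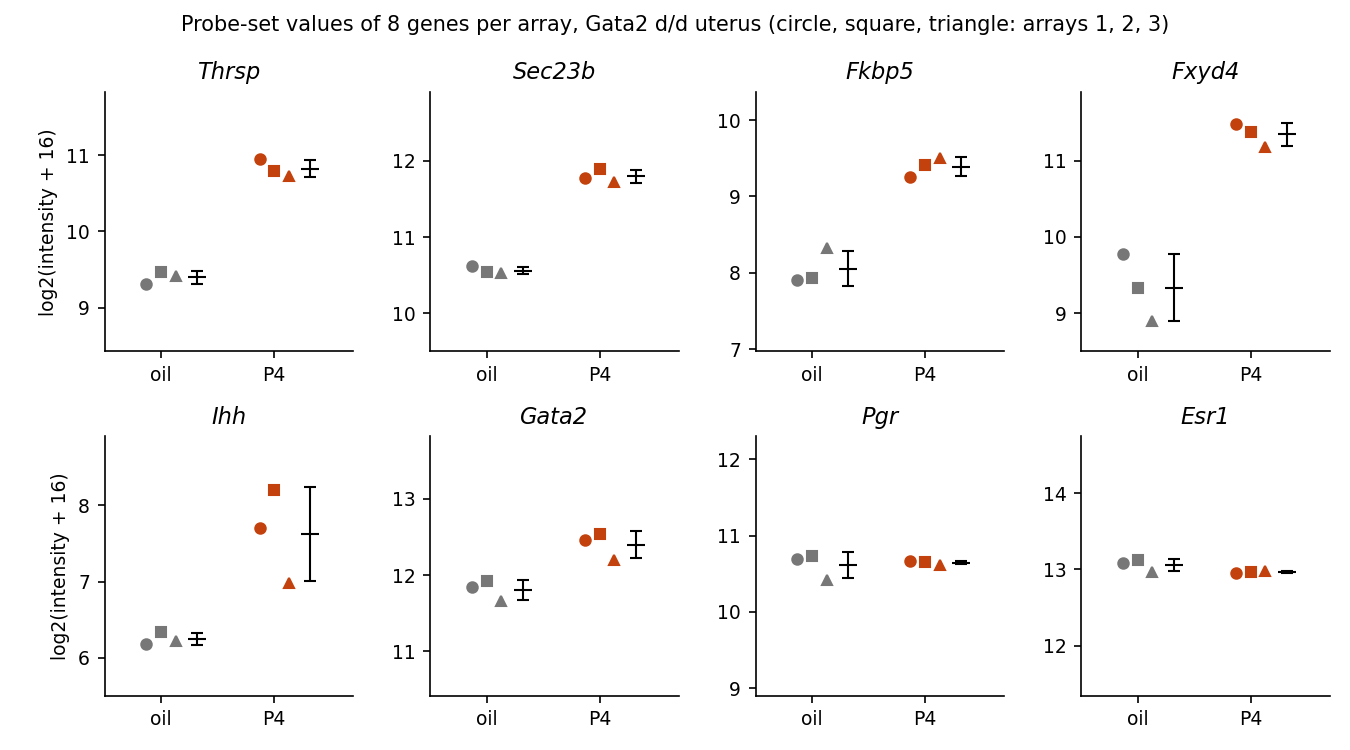
Log2(intensity + 16) of 8 genes in the 3 oil arrays (grey) and 3 P4 arrays (orange), with the mean and SD beside each group; every panel spans the same number of log2 units. The P4 arrays lie above the oil arrays for Thrsp, Sec23b, Fkbp5, Fxyd4, Ihh and Gata2, while Pgr and Esr1 differed by 0.03 and -0.09.

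Among the genes with the next smallest p, none passed the threshold. Values higher in P4 were found for Cited4, a transcriptional coactivator (log2 difference 1.09), Hook1, a microtubule-binding protein (1.33), Abcc4, an exporter of cyclic nucleotides (0.87), and Hopx, a homeodomain protein (0.77), each at an adjusted p of 0.0502. Npl, an enzyme that breaks down sialic acid, differed by 2.22 ± 0.26 (SE; adjusted p = 0.0516) and Zmpste24, a protease that matures lamin A, by 0.81 (adjusted p = 0.0951). Cited4, Hook1, Abcc4 and Hopx were past the threshold with weights on the arrays and with a trended, robust variance, and Npl and Zmpste24 with array weights. Leaving out P4 array 3 brought Cited4, Hook1 and Npl past it (adjusted p = 0.0468, 0.0343 and 0.0415), leaving out oil array 2 did so for Hook1 (0.0412), and leaving out P4 array 2 for Npl (0.0237). The array weights were lowest for oil array 3 (0.515) and P4 array 3 (0.606), against 1.14 to 1.44 in the others. A pass with array weights is therefore not independent of a pass without those arrays. Values lower in P4 were led by the chemokine receptor gene Cxcr4, at -0.70 ± 0.097 (SE; adjusted p = 0.102), and the phospholipid acyltransferase gene Mboat7, at -0.41 (adjusted p = 0.183). Parm1, Cpxm1, Tfb1m, Trib2, Serpinb1a, Scel, Maged2 and Ankrd29 followed, with differences between -0.63 (Ankrd29) and -0.34 (Trib2) and adjusted p between 0.232 and 0.444.

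The targeted gene, Gata2, gave intensities of 3575 ± 320 in oil and 5410 ± 646 in P4 (SD, n = 3), and its probe sets differed by 0.59 and 0.62 on the log2 scale (adjusted p = 0.251 for the first). The sources used here do not say which part of Gata2 was removed, and no array with intact Gata2 was analysed here, so these values check neither the genotype nor the extent of the deletion. The progesterone receptor gene Pgr differed by 0.03 (adjusted p = 0.959), the estrogen receptor gene Esr1 by -0.09 (adjusted p = 0.817) and the glucocorticoid receptor gene Nr3c1 by -0.20 (adjusted p = 0.785). The signs of Pgr and Esr1 turned when all probe sets of each gene were averaged, to -0.042 and 0.015.

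Genes known to be raised by P4 in the mouse uterus stood higher in the P4 arrays as a group. Of 23 measured members of the P4 response list, 20 had higher values in P4 and 3 lower, with a mean log2 difference of 0.40 and a median of 0.45. The P4 arrays that carried this shift were also those with the higher 3'/5' ratios of Actb and Gapdh. Over all genes tested, 1 member (Fkbp5) rose. With p adjusted over the list alone, 13 rose, none fell and 10 did not pass. Those 13 included Ihh, the hedgehog ligand of the uterine epithelium (1.38 ± 0.26), Hdc, the histamine-making enzyme (1.23 ± 0.16), Il13ra2, a decoy receptor for interleukin 13 (0.56 ± 0.079), and the homeobox gene Hoxa10 (0.55 ± 0.09; all SE). Ihh and Il13ra2 were dim, where array medians were 113.2 to 120.0. Ihh had intensities of 60.1 ± 4.3 in oil and 193.6 ± 84.1 in P4 (SD, n = 3). Il13ra2 had 62.5 ± 4.0 and 99.8 ± 6.0 (SD, n = 3), and such values can lie near background. The others were Fkbp5, Gata2, Sgk1 (0.73), Zbtb16 (0.76), Errfi1 (0.66), Per1 (0.45), Hsd11b2 (0.75), Ptch1 (0.32) and Hoxa11 (0.46). Members that did not pass included Hand2 (0.13), Nr2f2 (0.12), Cyp26a1 (0.11), Lrp2 (0.095) and Tsc22d3 (0.16), while 2 dimmer probe sets of Lrp2 differed by 0.97 (unadjusted p = 0.000105) and 0.67 (unadjusted p = 0.00306). The 3 members with lower values were Fst (-0.40), Alox15 (-0.48) and Acod1 (-0.70). Without oil array 3 the values of Cyp26a1 and Tsc22d3 turned to -0.10 and -0.075, without oil array 1 that of Lrp2 to -0.12, and without oil array 3 that of Acod1 to 0.36. Hdc was past the threshold over all genes without oil array 3 (adjusted p = 0.0305) and with array weights (0.0247). Without P4 array 3, Ihh and Sgk1 were past the threshold over all genes (adjusted p = 0.0415 and 0.0343). The list passed camera with a preset correlation of 0.01 (adjusted p = 2.13e-11) and fry (adjusted p = 0.0133), but the adjusted p was 0.115 with an estimated correlation. Areg and Calca were not analysed here.

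**Figure D2:**
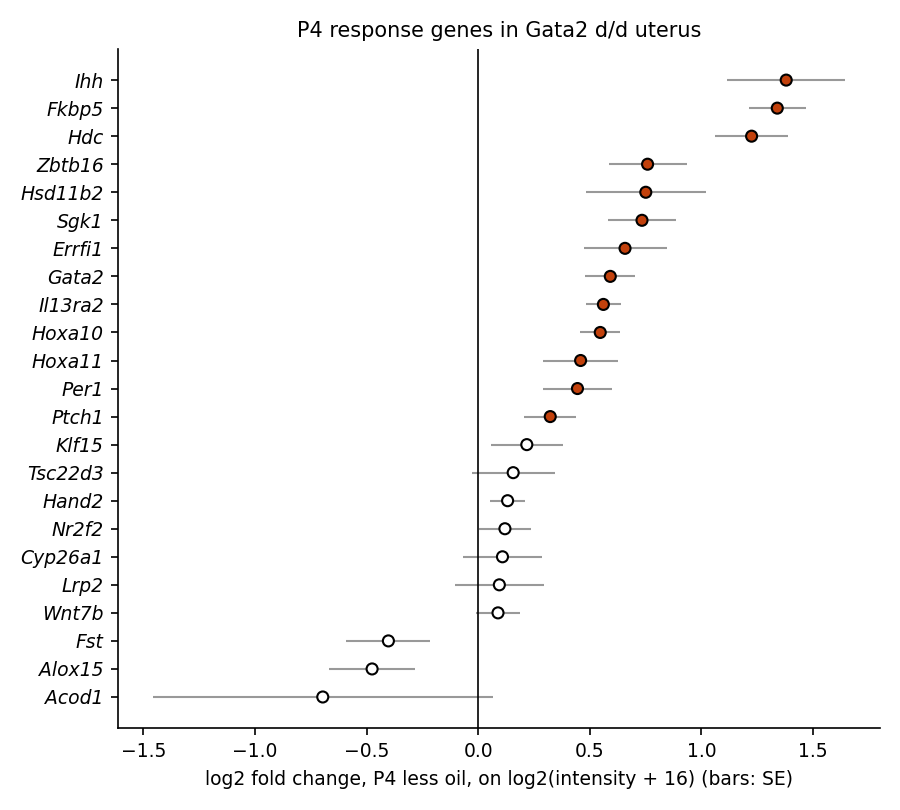
Log2 fold change (P4 less oil) with its SE for the 23 measured genes of the P4 response list; filled points passed with p adjusted over the list alone. The 13 filled points run from 0.32 for Ptch1 to 1.38 for Ihh, and Fst, Alox15 and Acod1 lie below 0.

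Glucocorticoid-type targets, which overlap with the P4 response list, had higher values in P4 as well. Among 24 members of the list of glucocorticoid-type steroid targets, 20 had higher and 4 lower values in P4, with a mean log2 difference of 0.29 and a median of 0.17, again in the arrays with the higher 3'/5' ratios. Over all genes 1 rose (Fkbp5), and adjusted over the list alone 6 rose, none fell and 18 did not pass. The 6 were Fkbp5, the metallothionein genes Mt1 (0.70 ± 0.10) and Mt2 (0.69 ± 0.12), the kinase gene Sgk1 (0.73 ± 0.15), Zbtb16 (0.76 ± 0.18) and Errfi1 (0.66 ± 0.19; all SE). The list passed camera with the preset correlation (adjusted p = 3.36e-06) and fry (adjusted p = 0.00378), and its adjusted p was 0.2 with an estimated correlation. The 7 members shared with the P4 response list had a mean of 0.62, all higher. The other 17 had a mean of 0.16 and a median of 0.043, 13 of them higher, and a camera p of 0.0103 with the preset correlation and 0.0661 with an estimated one, in a split of the list made after seeing the data. The list is therefore not a result independent of the P4 response list.

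Hedgehog genes showed higher values on the whole, without passing the list test. Of 17 members, 12 were higher and 5 lower in P4, the mean was 0.17 and the median 0.092, and the adjusted p in camera was 0.0538. It was 0.699 in camera with an estimated correlation and 0.434 in fry. Ihh, Ptch1 and Nr2f2 are also on the P4 response list, so the hedgehog list is not independent of it. Only Ihh rose with p adjusted over the list alone, and 16 did not pass, among them the target genes Gli1 (0.61 ± 0.19), Hhip (0.30 ± 0.09) and Ptch1 (0.32 ± 0.12; all SE). The list was past the threshold with the arrays quantile normalized (adjusted p = 0.0446), with the arrays centred on their medians (0.0391), without oil array 2 (0.0258), without P4 array 3 (0.00492) and with array weights (0.0224). The epithelial transport genes were mixed, since 3 of 23 members of the ion and water transport list rose over the list alone, Fxyd4, the sodium pump subunit Atp1b1 (0.46 ± 0.084) and the sodium channel subunit Scnn1a (0.43 ± 0.086), while Scnn1b was at -0.25 ± 0.12 (SE). That list had a mean of 0.081 and an adjusted p of 0.158 in camera. Without P4 array 3 its adjusted p was 0.032 and with array weights 0.0445.

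No shift in a common direction was detected in the Wnt and growth factor pathways. None of 49 Wnt pathway members and none of 39 BMP and TGF-beta members passed adjusted over their lists, the means were 0.002 and -0.024, and camera gave adjusted p of 0.984 and 0.472. Within them Wnt4 differed by 0.76 ± 0.32 (also on the estrogen and decidual lists), Wnt16 by -0.49 ± 0.15, Bmp2 by -0.19 ± 0.14 and Inhba by -0.27 ± 0.097 (SE). The mean of the Wnt list turned to -0.016 with quantile normalization and to -0.029 with the arrays centred. Camera as used here does not see members that move in opposite directions. The form of fry that counts changes either way gave unadjusted p of 0.0125 for Wnt and 0.197 for BMP and TGF-beta. Among 26 decidual stroma genes Hoxa10 rose over the list alone and 25 did not pass, with Il15 at -0.28 and Hoxa11 at 0.46 (list mean 0.036, adjusted p = 0.804). The retinoid list had 18 members, none passing, with Cyp26b1 at -0.23 and Dhrs3 at -0.26, and its adjusted p was 0.568. Its median, 0.003, and its mean, -0.048, differ in sign.

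Among steroid receptors and estrogen-responsive genes, single members passed, all but Fkbp5 only with p adjusted over the list alone, and the lists did not. Of 17 steroid receptors and cofactors, Fkbp5 rose and 16 did not pass, among them the glucocorticoid-inactivating enzyme gene Hsd11b2 (0.75) and its counterpart Hsd11b1 (-0.39), with a list mean of 0.11 and an adjusted p of 0.246. Of 25 estrogen-responsive genes, Greb1 rose over the list alone (0.51 ± 0.11, SE) and 24 did not pass, including Ltf at -0.47, Muc1 at -0.45 and Car2 at 0.35. The adjusted p of the estrogen list was 0.394, with a median of 0.017, an upward test and a mean of -0.015. Without oil array 3 its mean was 0.197 (adjusted p = 0.00724), without P4 array 3 it was 0.088 (adjusted p = 0.0191), and with array weights 0.149 (adjusted p = 0.0224). Of 8 GATA and FOG factors, Gata2 rose over the list alone and 7 did not pass, with Gata4 at -0.16 and Gata5 at 0.12. The median of that list was -0.004, its mean 0.072 and its test upward (adjusted p = 0.394).

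Cell cycle, stress and clock genes did not pass, either as lists or as single members. None of 35 cell cycle members passed, with Tyms at 0.37 and Mcm6 at -0.44. Their mean of -0.002 and their upward test differ in sign (adjusted p = 0.998). The cell cycle list mean was -0.23 without oil array 1 (adjusted p = 2.44e-05), 0.18 without oil array 3 (adjusted p = 0.00741), 0.16 without P4 array 3 (adjusted p = 0.0425) and 0.16 with array weights (adjusted p = 0.0224). None of 24 immediate early genes passed, although Egr2 (-0.68 ± 0.16) and Egr1 (-0.37 ± 0.10; SE) were lower in value, and the adjusted p of that list was 0.422 with a mean of -0.054. None of 20 heat shock genes passed, with Trib3 at -0.33 and Hspa1b at 0.44 (mean 0.018, adjusted p = 0.954), and the mean turned to -0.012 with the arrays centred. None of 17 clock genes passed, with Nfil3 at 0.72 and Per1 at 0.45. The clock list had a mean of 0.11 and an adjusted p of 0.122, which was 0.0403 without oil array 2 and 0.0304 without P4 array 1. None of 18 prostaglandin genes passed, with Hpgd at -0.39 and Ptger1 at 0.20. Their mean was -0.13 and the adjusted p 0.127, or 0.0317 without oil array 2.

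Among markers of the tissue's own cells, 3 epithelial genes passed with p adjusted over their list alone, and no list passed. None of the 3 passed over all genes (adjusted p in limma from 0.126 to 0.472). Of 21 luminal and general epithelium markers, the tight junction gene Cldn3 (0.88 ± 0.14) and the epithelial transcription factor genes Ehf (0.64 ± 0.11) and Grhl2 (0.42 ± 0.10; all SE) rose over the list alone, and 18 did not pass, with Lamb3 at -0.30. The epithelium list had a mean of 0.13 and an adjusted p of 0.055. It was past the threshold with quantile normalization (0.0285), with the arrays centred (0.0263), without oil array 2 (0.00576), without P4 array 3 (3.08e-05, mean 0.248) and with array weights (0.00456). These p are from camera at the preset correlation of 0.01. The estimated correlation of the epithelium list was 0.524, and with it the adjusted p over the 6 arrays was 0.811. None of 12 gland markers passed, with Sox17 at 0.43 and Foxa2 at 0.34, and the list mean was 0.11 (adjusted p = 0.114, or 0.0335 without P4 array 3 and 0.044 with array weights). None of 18 stromal, 18 smooth muscle or 18 endothelium markers passed, with Lum at -0.32, Kcnmb1 at -0.29 and Flt4 at -0.20 nearest to passing. The means were -0.029, -0.057 and -0.076 and the adjusted p 0.568, 0.214 and 0.147. The smooth muscle list was past the threshold without oil array 1 (0.0479) or P4 array 3 (5.82e-05) and with array weights (0.0445). The endothelium list was so without oil array 2 (0.0348), oil array 3 (0.00741) or P4 array 3 (0.00123) and with array weights (0.00869), while its mean turned to 0.033 without oil array 1 and 0.031 without P4 array 2. The p of both lists are again at the preset correlation, while the estimated ones were 0.474 for smooth muscle and 0.745 for endothelium. With those, camera gave each list an adjusted p of 0.827 over the 6 arrays.

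Markers of the outer mesothelium passed the list test downward only with the preset correlation. Of 8 members, Lrrn4 (-0.40 ± 0.079) and Upk3b (-0.41 ± 0.11; SE) fell over the list alone, none did over all genes, and 6 did not pass, with Gpm6a at -0.41 and Upk1b at -0.32. By value 5 members were lower and 3 higher. The mesothelium list had a mean of -0.2 and an adjusted p of 0.0183 in camera, against an adjusted p of 0.519 with an estimated correlation and 0.348 in fry. The list was lower in all 3 P4 arrays, which were also those with the higher 3'/5' ratios of Actb and Gapdh. Its adjusted p was 0.0833 without P4 array 2, where the mean was -0.13, and 0.0882 with dim probe sets left out. Lists of neighbouring tissues did not pass. Among 11 adipocyte markers Thrsp rose and 10 did not pass. The secreted fat-cell product Adipoq was at -0.998 ± 0.60 and Retn at -0.65 ± 0.25 (SE), with a list mean of -0.23 and an adjusted p of 0.214. That p was 0.0348 without oil array 2 and 0.0282 without P4 array 3, both at the preset correlation. With the adipocyte list's estimated correlation of 0.321, camera gave an adjusted p of 0.811 over the 6 arrays. None of 13 skeletal muscle markers passed (mean -0.045, adjusted p = 0.886), with Tnni2 at -0.34 and Acta1 at -0.41, and Acta1 turned to 0.062 without oil array 3. Among 12 oviduct and ovary markers the secreted glycoprotein gene Ovgp1 rose over the list alone (1.34 ± 0.18, SE) and 11 did not pass, with Tekt1 at -0.22. Without oil array 2, Ovgp1 was past the threshold over all genes (adjusted p = 0.0279). The oviduct list had a median of -0.04, a mean of 0.067 and an adjusted p of 0.963. The red blood cell list had 4 measured members, none passing, with differences between -0.10 (Alas2) and -0.009 (Slc4a1), and was too short to test.

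Interferon-response and macrophage genes had lower values in P4 as groups, although no member passed either over all genes or over its list alone. All 22 interferon-response members were lower, by a mean of -0.39, among them Ifit3 (-0.84 ± 0.28), Usp18 (-0.72 ± 0.27), Rsad2 (-0.44 ± 0.16) and Xaf1 (-0.32 ± 0.096; all SE). Camera gave the interferon list an adjusted p of 1.37e-08, and with an estimated correlation the adjusted p was 0.699. Oil array 3 stood apart in these genes, with a list mean of 0.68 against at most -0.028 in any other array, and the shift was -0.14 without it. All 3 P4 arrays, which had the higher 3'/5' ratios of Actb and Gapdh, lay below all 3 oil arrays in the interferon list. Of 20 macrophage and myeloid markers 19 were lower, by a mean of -0.58, with Fcer1g at -1.37 ± 0.54, Tyrobp at -1.03 ± 0.41 and Ptprc at -0.82 ± 0.36 (SE). The macrophage list had an adjusted p of 3.36e-06 in camera and an adjusted p of 0.805 with an estimated correlation. Here oil array 1 stood apart, at 0.98 against at most 0.28 in any other array, and the shift was -0.23 without it and -0.92 without oil array 2. The groups overlapped in the macrophage list, as oil array 2, at -0.396, lay below P4 array 1 (-0.047) and P4 array 3 (-0.31).

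Other immune lists did not pass. None of 16 lymphocyte markers passed, with Cd79b at -0.59 and Ccl5 at -0.58. Their mean was -0.14 and the adjusted p 0.0871, or 0.00147 without oil array 2. Of 16 granulocyte and mast cell markers Hdc rose over the list alone and 15 did not pass, with Cma1 at -0.49 ± 0.34 and Mcpt4 at -0.28 ± 0.11 (SE). The granulocyte list had a mean of -0.23 and an adjusted p of 0.376. Without oil array 2 the mean was -0.47 (adjusted p = 0.0403), and without oil array 3 it turned to 0.069.

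**Figure D3:**
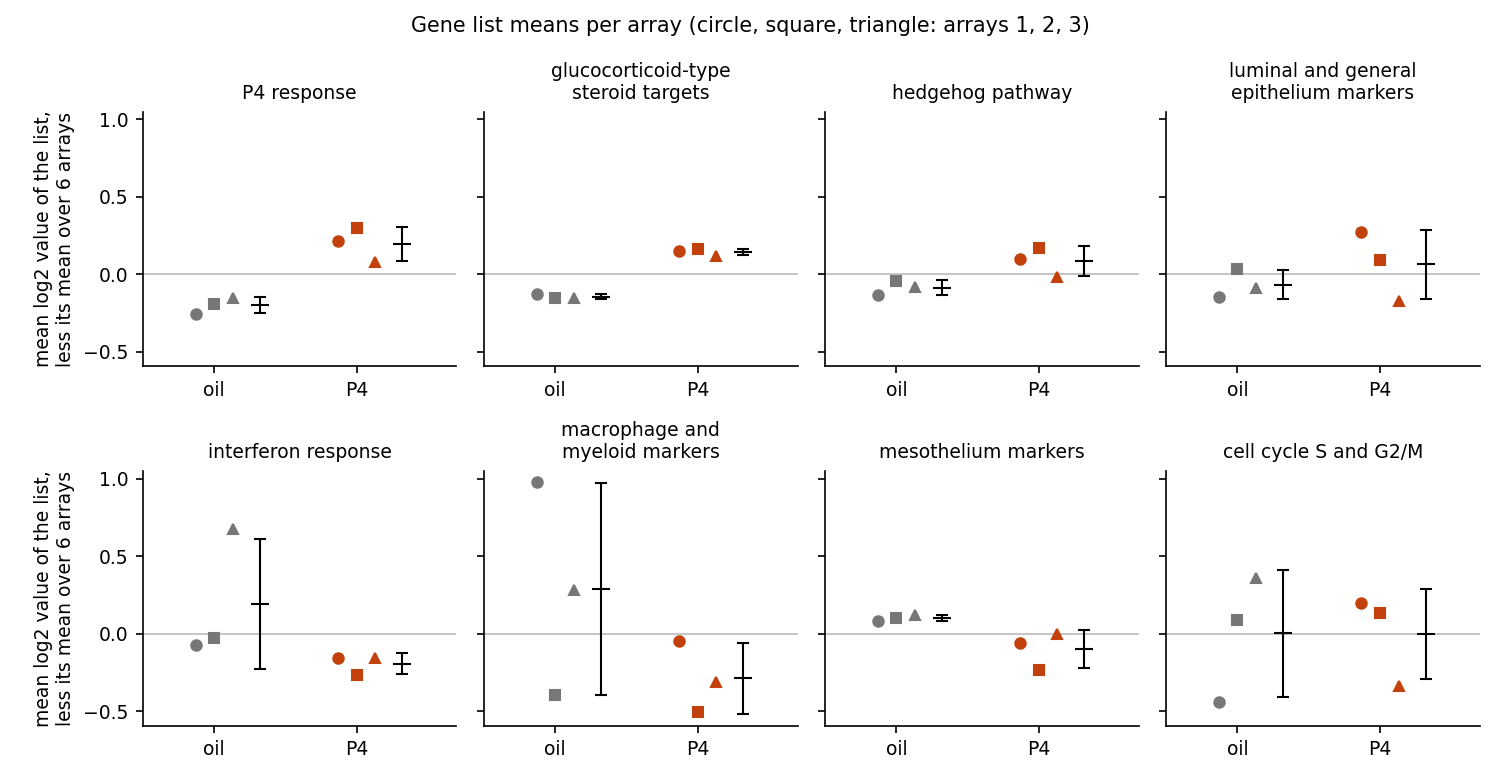
Mean log2 value of 8 gene lists in each array, less the list's mean over the 6 arrays, with the mean and SD of each group beside the 3 oil (grey) and 3 P4 (orange) arrays. For the P4 response and glucocorticoid-type lists all P4 arrays lie above all oil arrays, while oil array 3 leads the interferon list at 0.68 and oil array 1 the macrophage list at 0.98.

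In all, 5 of 29 lists passed camera with the preset correlation, 2 higher and 3 lower in P4, against 4 higher and 3 lower after quantile normalization or centring. None of them passed with an estimated correlation, and 2, the P4 response and glucocorticoid-type lists, passed fry.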

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

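The tests of RNA degradation and of P4 treatment were chosen after the values had been seen. The test of RNA other than spliced mRNA was written before its result.

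Control probe sets for 18S ribosomal RNA, outside the genes compared, were brighter in the highest P4 array than in the highest oil array, by 2.8 times for the 3' probe set, 2.73 times for the middle one and 2.4 times for the 5' one. The P4 array was number 3 each time, with a 5' intensity of 11045 against 4608 in oil array 1 and 679 to 1926 in the other 4 arrays. The values argue against P4 treatment, since 1 P4 array lay above the oil arrays, while RNA degradation stays open: the Actb 3'/5' ratio of P4 array 3 was 2.13, above every oil array but below the 2.27 of P4 array 1, where the 5' 18S intensity was 679, and its Gapdh ratio of 1.73 was level with that array. RNA other than spliced mRNA in that sample also stays open and may account for the signal, as probe sets with no gene symbol stood highest there against named ones, at -0.703 on the log2 scale against at most -0.812 in the other arrays. Where such RNA would come from was not tested.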

How the results depend on the processing

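A list's direction is read here as the sign of its mean log2 difference, a convention settled after the tables had been seen. The subsets of the P4 response and glucocorticoid-type lists without their shared members, and the fit with the 3'/5' ratios were added after seeing the data. The count of 4 called genes was 4 with quantile normalization, with centring and with a fold change of at least 1.5, and 3 without dim probe sets. Over all probe sets, 3 probe sets of 2 genes, Thrsp and Sec23b, were called. It was 2 with the mean of a gene's probe sets, 2 with a pseudocount of 1, 2 with a pseudocount of 64, 2 when tested against a fold of 1.2, 8 with a trended robust variance, 14 with array weights, 15 at an adjusted p under 0.1, and 1 to 13 with an array left out. The looser threshold changes the count by construction, and otherwise the cause was not tested. The count of 5 lists was 13 with array weights, 0 with an estimated correlation, 2 with fry and 4 to 14 with an array left out. With the replicate number as a block it was 11, while the same 4 genes were called. The lists it added were hedgehog (adjusted p = 0.0198), adipocyte (0.0198), lymphocyte (0.0203), epithelium (0.0303), gland (0.0432) and prostaglandin (0.0432). Arrays with the same number did not deviate together (correlations of -0.13, 0.023 and -0.304), so these values give no sign that the numbers pair the samples. They cannot rule out a shared block, as each deviation is from a mean of only 3 arrays. Of 2215 values of 149 genes under the settings, 2153 kept direction and side of the threshold, 18 fell short of it, 25 came past it and 19 turned. Of 493 list values, 423 kept both, 10 fell short, 35 came past and 25 turned. Under fry the Wnt and adipocyte lists had a direction opposite to camera's.

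None of the genes and lists that turned was past the threshold in the main setting, and the cause was not tested. With array weights the turned cell cycle and estrogen lists were past it in camera at the preset correlation (adjusted p = 0.0224 for both). With quantile normalization the Wnt list was at -0.016. With the arrays centred it was at -0.029 and the heat shock list at -0.012. With the mean of a gene's probe sets Pgr was at -0.042 and Esr1 at 0.015. With array weights Pgr was at -0.016, Cyp26a1 at 0, Hba-a1 at 0.022, and the lists of cell cycle at 0.164, estrogen-responsive genes at 0.149 and stromal fibroblasts at 0.015. With a pseudocount of 1 the cell cycle list was at 0.001. With an array left out, the log2 difference ran from -0.118 to 0.245 for Lrp2, -0.068 to 0.09 for Pgr, -0.104 to 0.268 for Cyp26a1, -0.075 to 0.291 for Tsc22d3, -0.747 to 0.062 for Acta1, -0.231 to 0.021 for Alas2, -0.127 to 0.065 for Slc4a1, -0.117 to 0.017 for Hba-a1 and -1.25 to 0.358 for Acod1. For list means it ran from -0.026 to 0.05 for Wnt, -0.07 to 0.079 for heat shock, -0.162 to 0.033 for endothelium, -0.225 to 0.177 for cell cycle, -0.17 to 0.197 for estrogen-responsive genes, -0.073 to 0.02 for stromal fibroblasts, -0.47 to 0.069 for granulocytes, -0.092 to 0.015 for skeletal muscle and -0.004 to 0.075 for decidual stroma. Dim probe sets limit precision, as the file gives no signal over background.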

Other observations

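All tests named here were chosen after the results had been seen, except the splits of the arrays. The test of P4 response members off the glucocorticoid-type list was added after seeing the data but written before its own result.

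Single oil samples stood apart from the rest. In oil array 3, 64 genes stood over 1 log2 unit above every other array. Against the mean of the other oil arrays, the widest gaps in oil array 3 were those of the acute-phase gene Saa3 (6.62 log2 units higher), the neutrophil attractant Cxcl5 (6.32), the neutrophil proteins S100a9 (5.57) and S100a8 (5.28), the chemokine Cxcl2 (4.99), the estrogen-responsive epithelial gene Sprr2f (4.93) and Olfm4 (4.53). In oil array 1, 34 genes stood over 1 unit above every other array, and the widest gaps were those of the macrophage genes Fcrls (3.10), Adgre1 (2.88) and Ly86 (2.63). No more than 1 gene did in any other array. The first principal component, 39.2% of the variance, placed oil array 3 at 30.7 and the others at -1.72 or below. These genes were picked after their values were seen.

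At an adjusted p under 0.1, limma gave 15 genes, all higher in P4. Besides those named in the comparison, they were Slc25a48, a mitochondrial carrier (1.17 log2 units), the phospholipase Pla2g10 (1.22) and Lpar3, a lysophosphatidic acid receptor of the uterus (0.80), with adjusted p of 0.0502, 0.0875 and 0.0951. Slc25a48, Pla2g10 and Lpar3 were past the threshold with array weights (adjusted p = 0.0236, 0.0422 and 0.0236), Slc25a48 also with a trended, robust variance (0.0295) and Lpar3 also without P4 array 3 (0.0415). These too were named after their values were seen.

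The lower interferon and macrophage lists in P4 were set against single oil samples. Without oil array 3, 37.1% of the interferon shift was left, and without oil array 1, 40.3% of the macrophage shift, so an excess in single oil samples may account for most of each. RNA degradation in oil array 3 is argued against, as its Actb 3'/5' ratio was 1.82, the lowest of the arrays, with 2.27 the highest. An effect of P4 on the remainder stays open, untested. The number of lists passing camera does not set the P4 and oil groups apart from other groupings, as the real split of the 6 arrays gave 5 lists and 9 of 10 splits gave as many or more, up to 15, and 10 splits cannot give a share under 0.05.

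The P4-raised genes were set against the make-up of the samples. A larger share of epithelium in the P4 arrays is argued against as the whole account. The epithelium markers had a median difference of 0.094 (SD 0.27 over members) where the P4 response list had 0.445. In P4 array 3 the epithelium list, at -0.171, was below every oil array. There the P4 response list, at 0.081, was above every oil array. A part played by epithelium stays open, as P4 arrays 1 and 2 stood at 0.276 and 0.09 in the epithelium list, against at most 0.037 in oil. The RNA of P4 array 3 is argued against too as the source of the shift. Its P4 response mean of 0.081 was below those of P4 arrays 1 (0.215) and 2 (0.299). That 115% of the list's shift was left without P4 array 3 follows from these values and is no separate test. The 16 members off the glucocorticoid-type list had a mean of 0.30, 13 of them higher. Their camera p with an estimated correlation was 0.0143, not adjusted over the lists. At that unadjusted level it argues against those shared targets alone. The whole P4 response list had an unadjusted p of 0.00396 in the same test and did not pass once adjusted (0.115). Of the 10 splits of the 6 arrays, 1, the real one, gave as many as 4 genes (highest other 1), and 1 gave a P4 response shift of 0.397 (highest other 0.242), but 10 splits cannot give a share under 0.05. RNA degradation stays open, since the Actb and Gapdh 3'/5' ratios were higher in every P4 array than in every oil array: with them in the fit 119% of the list's shift was left, but its 95% interval ran from -0.08 to 1.02. Any part played by Gata2 was not tested, as no array with intact Gata2 was analysed here.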
